A study of Mus musculus with 12 samples.

How the data were processed

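Bulk RNA sequencing was done on mouse samples labelled as natural killer (NK) cells, taken from spleen and from tumor of control (WT) mice and of mice with a conditional knockout (cKO) of 1 gene. The 12 libraries fall into 4 groups of 3, spleen WT, spleen cKO, tumor WT and tumor cKO, per the labels. The labels do not say whether the libraries of a group came from separate animals, so all p-values measure only the spread between these samples. The gene that was knocked out is not reported here, so the genotype labels were not checked against its level. Total RNA was isolated with TRIzol and sequenced on a NovaSeq 6000.

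The authors mapped the reads to the mouse genome GRCm38 (mm10) with TopHat2 2.0.6, per the labels. The counting program, its version and its strand setting, and any trimming or read filter, are not given in the sources used here. The authors deposited a table of counts, whole numbers of reads per gene without normalization, for 33100 gene rows with a position and a length for each. Between 68.8% and 73.3% of the counts from 1 to 49 were even numbers, as when both mates of a read pair are counted, so the counting noise is larger than the counts alone imply. The authors also deposited a table of RPKM values, counted reads per kilobase of listed length scaled to the library total. Each nonzero RPKM value matched the one computed from the count table within a relative tolerance of 0.0001 in 100% of cases. Gene positions were checked against the GENCODE vM21 annotation of GRCm38, in which 31654 of the symbols were found. Of these, 31640 overlapped the annotated position and 28162 had the same start and end. Coordinates are those of the count table, on GRCm38.

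Totals per library ranged from 9542329 to 37118494 counts. A gene without reads in all 3 libraries of a group was set against a floor of 3 counts over the group, which as a counts-per-million (CPM) level is 0.0811 in spleen WT, 0.0797 in spleen cKO, 0.0434 in tumor WT and 0.0456 in tumor cKO. Folds against such a group are given as "at least" and set the pooled reads of the other group, over its pooled scaled totals, against the floor. Where that exceeded the fold of the mean over the floor, the level alone is given. These floors cover counting error only. Levels are CPM over library totals scaled with the composition factors described next, as mean ± SD of 3 libraries, and fold changes are log2 values ± SE from the fit.

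Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 4 groups, which left 16831 genes tested. Libraries were scaled with TMM factors, which lay between 1.008 and 1.046 in spleen, 0.896 and 0.957 in tumor WT, and 1.032 and 1.055 in tumor cKO. A quasi-likelihood model with robust dispersion and 1 mean per group was fitted to all 12 libraries with 8 residual degrees of freedom, and the common dispersion was 0.08. The comparisons were cKO against WT in spleen and in tumor, tumor against spleen in WT and in cKO, the difference of the cKO effects between the tissues, and the cKO effect averaged over both. Tests were two-sided quasi-likelihood F-tests, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. All adjusted p-values of genes are from edgeR unless another tool is named. The replicate number was not used as a block, because the labels do not say that it marks a shared animal or day.

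A set of 31 gene lists, 20 of NK cell functions and cell states and 11 of markers of other cell types, was compared with all other genes by camera of limma 3.58.1. It used log2 CPM values with TMM factors and a prior count of 2, and a preset correlation between genes of 0.01. Lists with at least 5 tested genes were tested, and p was adjusted over the lists of a comparison. The lists held 633 entries, of which 8 symbols had no row in the count table. Beside each list stand the number of members called over all genes and the number called when p was adjusted over the list alone. Camera was repeated with a correlation estimated for each list, and no list of any comparison was called then. Overlaps of calls were tested with Fisher's exact test, one-sided.

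The genes named for a comparison were those called with a mean log2 CPM of at least 2 over the 12 libraries, with groups whose CPM did not overlap, and with a symbol of neither a predicted model nor a pseudogene. Chance alone gives no overlap for 10% of genes with 3 against 3 libraries. Of these genes the 10 with the largest rise and the 10 with the largest fall were taken for cKO against WT in each tissue, for tumor against spleen in WT and for the average. For the difference between tissues the 5 largest in each direction were taken. Where fewer than 5 passed in a direction, the 5 of smallest p were added and are given as not passing. Named as well were Pdcd1, Il2rb, Il2rg, Il15ra, Ptpn6, Ifng, Gzmb and Prf1, and up to 4 members of each list. Of the genes chosen in these ways, 3 are not reported here. The tests, lists, comparisons, naming rule and most alternatives were fixed before the data were examined.

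The steps were tested on simulated data, counts drawn with the means and spread of these libraries, in which 200 genes were changed, 100 of them 4-fold and 100 of them 2-fold. With all 12 libraries in 1 fit, 79% of the 4-fold and 52% of the 2-fold changes placed in spleen were called, and 3.7% of the calls were unchanged genes. For changes placed in tumor the shares were 70% and 41%, and 28.8% of the calls, 45 of 156, were unchanged genes. A fit of the 6 libraries of 1 tissue recovered 87% and 73% in spleen with 5.3% unchanged genes among the calls, and 66% and 16% in tumor with 3.5%. The total count of tumor calls from the 6 tumor libraries alone is therefore given as well. Counts within lists, for the difference and for the average are from the 12-library fit.

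Alternatives tried were DESeq2 size factors, no composition factor, no filter on low counts, a stricter filter of 1 CPM in 3 libraries, a log2 fold change of at least 1 in size, the replicate number as a block, and only the libraries of the groups compared. Others were DESeq2 1.42.0, limma-trend on log2 of the authors' RPKM plus 0.5, and leaving out each library in turn. For lists, an estimated correlation, the test fry of limma, no composition factor and the block were tried. Chosen after seeing the data were a fit without tumor WT replicate 2 and tumor cKO replicate 3, which stood apart from their groups, and a fit with a macrophage score as a covariate.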

Results

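RNA levels were measured by bulk RNA sequencing in samples labelled as NK cells from spleen and tumor of WT and cKO mice, with 3 libraries in each of the 4 groups. The spleen WT libraries held 12893957, 13105059 and 10496256 counts for replicates 1, 2 and 3, and the spleen cKO libraries 13387157, 9542329 and 13753737. The tumor WT libraries held 18967908, 37118494 and 18518070 counts. The tumor cKO libraries held 22685684, 15765906 and 24832976. Between 18466 and 19500 genes had reads in a spleen library, and between 21503 and 25609 in a tumor library. Mitochondrial transcripts took 0.819% to 1.069% of the counts in spleen and 1.702% to 3.018% in tumor. Pearson correlations of log2 CPM between libraries of a group were 0.9896 to 0.9933 in spleen, 0.9739 to 0.9913 in tumor WT and 0.9883 to 0.993 in tumor cKO.

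The levels of the lineage markers Ncr1, Klrb1c, Pax5 and Lyz2 did not overlap between the tissues. Those of the macrophage gene Cd163 did, at 11.3 to 18.9 CPM in spleen cKO and 9 to 11.4 CPM in tumor cKO. Ncr1, the activating receptor NKp46 of NK cells, was at 90.9 to 204 CPM in the 6 spleen libraries and at 0.42 to 1.86 CPM in the 6 tumor libraries. Klrb1c, which encodes the NK1.1 antigen, was at 113 to 170 CPM in spleen and 1.01 to 8.09 CPM in tumor. Pax5, the transcription factor of B-cell identity, was at 466 to 649 CPM in spleen and at 0.12 to 6.46 CPM in tumor. Lyz2, the lysozyme gene of macrophages and granulocytes, was at 4.92 to 21.9 CPM in spleen and at 523 to 6638 CPM in tumor. Tumor WT replicate 2 stood apart from its group with Lyz2 at 6638 CPM. Its Col3a1, a fibrillar collagen gene, was at 848 CPM, against 97.6 and 44.2 CPM in replicates 1 and 3. Tumor WT replicate 3 stood apart with 1.274% of its counts in immunoglobulin genes, against 0.024% to 0.066% in the other 5 tumor libraries and 0.464% to 0.506% in spleen. Tumor cKO replicate 3 had the lowest Lyz2 of its group, 523 CPM against 1230 and 1335 CPM.

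**Figure D1:**
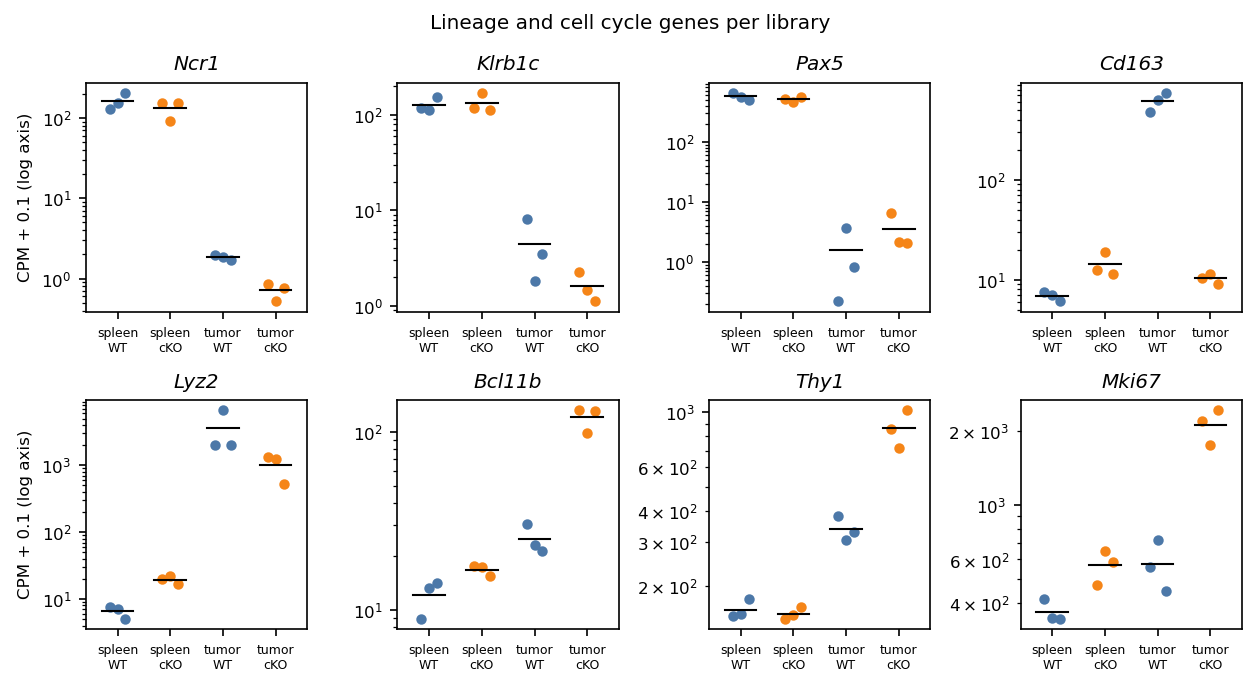
Levels of 8 lineage genes (Ncr1, Klrb1c, Pax5, Cd163, Lyz2, Bcl11b, Thy1 and Mki67) in the 12 libraries, as CPM plus 0.1 on a log axis, with 1 point per library and a line at the group mean. Ncr1 was at 90.9 CPM or more in every spleen library and at 1.86 CPM or less in every tumor library, and Cd163 was at 477 to 742 CPM in tumor WT and 9.0 to 11.4 CPM in tumor cKO.

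The comparison of cKO with WT in spleen asks how loss of the gene alters RNA levels in the samples labelled as NK cells of the spleen. Tcrg-C2, a constant-region gene of the T-cell receptor gamma locus (GRCm38 chromosome 13, 19304649 to 19307551), rose from 2.79 ± 0.455 CPM in WT to 6.87 ± 0.378 CPM in cKO (SD, n = 3 each; log2 fold change 1.29 ± 0.18 SE, adjusted p = 0.0303). The other 4 genes called, all higher in cKO, fell outside the naming rule and were chosen after their values were seen. They included Rps15a-ps6 (chromosome 11, 6172644 to 6173036; log2 4.86), which rose from 0.934 ± 0.506 to 27.9 ± 7.48 CPM, and Rps15a-ps7 (chromosome 2, 152185291 to 152185682; log2 3.61). The remaining pair were Trgj2 (chromosome 13, 19311245 to 19311304; log2 3.10) and 9130208D14Rik (chromosome 7, 105824223 to 105831515; log2 2.93). Rps15a-ps6 and Rps15a-ps7 are pseudogenes of the ribosomal protein gene Rps15a (chromosome 7, 118104372 to 118116188). Rps15a itself was at 136 ± 8.74 CPM in WT and 65.6 ± 26.6 CPM in cKO and did not pass by edgeR (log2 −1.05 ± 0.26, adjusted p = 0.684), but passed by DESeq2 (adjusted p = 0.0418) and without a filter (5.39e-07). Its log2 value without a filter was −1.052, so that lower adjusted p did not come from a larger change. Trgj2 is a joining segment of the same receptor locus as Tcrg-C2. Tcrg-C2 did not pass without spleen WT replicate 1 (adjusted p = 0.179), 2 (0.103) or 3 (0.217), without spleen cKO replicate 1 (0.158), 2 (0.134) or 3 (0.0814), or without tumor cKO replicate 1 (0.0532) or 2 (0.0703). Nor did it pass with the spleen libraries alone (0.173), with the replicate block (0.0586) or with a macrophage score of each library as a covariate (0.094).

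Among 16831 genes, edgeR called 5 as higher and 0 as lower in spleen cKO, and 784 genes had an unadjusted p under 0.05. DESeq2 called 46 genes, 40 higher and 6 lower, limma-trend on RPKM 8, and edgeR on the 6 spleen libraries alone 31, of which 3 were among the 5. Of the genes with the smallest p that did not pass, Rsad2, an antiviral interferon-induced gene, was at 1.74 ± 0.867 CPM in WT and 7.09 ± 0.851 CPM in cKO (log2 2.0 ± 0.38, adjusted p = 0.217). Inppl1, a phosphoinositide phosphatase, was at 17.1 and 40.4 CPM (log2 1.24 ± 0.23, adjusted p = 0.202). Ptpro, a receptor-type phosphatase, had no reads in spleen WT and was at 0.679 CPM in cKO, at least 8.19-fold higher (adjusted p = 0.0868). Cd163, the hemoglobin scavenger receptor of macrophages, was at 6.78 ± 0.754 and 14.2 ± 4.05 CPM (log2 1.06 ± 0.21, adjusted p = 0.27). Gas2l3 had a log2 value of 1.32 with the same adjusted p. On the lower side, Trim12a was at 236 ± 9.52 and 81.8 ± 53.4 CPM (log2 −1.53 ± 0.47, adjusted p = 0.894). Snora24, Crem and Ass1 had log2 values of −1.09, −0.91 and −0.70 without passing. The receptor and effector genes given next had adjusted p = 1 in spleen by edgeR. Il2rb was at 208 ± 30.9 and 204 ± 18.5 CPM and Gzmb at 79.9 ± 9.11 and 127 ± 35.3 CPM. The log2 values of Il2rg, Ptpn6, Ifng, Prf1, Pdcd1 and Il15ra were 0.03, 0.02, 0.13, 0.16, 0.42 and −0.76. The count of 5 rested on single libraries. It was 0 without spleen WT replicate 1, 2 or 3 or spleen cKO replicate 2 or 3, 1 without spleen cKO replicate 1 or tumor cKO replicate 1 or 2, and 8 without tumor WT replicate 2, where Inppl1 (adjusted p = 0.0144) and Ptpro (0.0203) passed. Other alternatives also called genes that did not pass above. Rsad2 passed with the spleen libraries alone (0.0267), with the replicate block (0.0348), by DESeq2 (0.000348), without a filter (2e-10) and without both tumor WT replicate 2 and tumor cKO replicate 3 (0.0208). Inppl1 passed with the spleen libraries alone (0.00199), by DESeq2 (0.000734), without a filter (8.69e-07) and without those 2 libraries (0.00237). Ptpro passed by DESeq2 (0.00721), without a filter (3.78e-06) and without those 2 libraries (0.0182). Cd163 and Crem passed by DESeq2 (0.00812 and 0.0418) and without a filter (5.13e-06 and 0.0218). Trim12a (1.89e-14), Gas2l3 (0.0279), Ass1 (0.0355) and Gzmb (0.0251) passed only without a filter. The log2 value of Trim12a was −1.524 without a filter and −1.526 with it, so its far lower adjusted p did not come from a larger change. That of Rsad2 moved as little (1.999 and 2.0), so passes without a filter are weak evidence.

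Of 30 lists tested in spleen, 6 were called by camera, although no single member passed over all genes. Cell cycle genes, 40 tested, had a median log2 value of 0.43 in cKO (adjusted p = 7.96e-14; adjusted p = 0.846 with an estimated correlation), and 5 were called higher when adjusted over the list alone. Mki67, a proliferation marker, was at 368 ± 39.9 and 569 ± 89.7 CPM, and Top2a, the topoisomerase of dividing cells, at 103 ± 12.6 and 168 ± 7.42 CPM. Interferon-stimulated genes, 33 tested, had a median of 0.46 (adjusted p = 4.19e-07; adjusted p = 0.846 with an estimated correlation), with 2 called higher adjusted over the list alone. Of these genes, Ifit1 was at 2.02 ± 0.999 and 5.37 ± 0.638 CPM. Markers of other cells moved the same way in these libraries. The 18 macrophage markers had a median of 1.14, or 1.05 with groups without reads at their floor (adjusted p = 1.6e-06). The median was 0.37 for the 15 T-cell markers (adjusted p = 0.00258) and 0.74 for the 8 erythroid markers (adjusted p = 0.000733). Each of these 3 lists had an adjusted p of 0.846 with an estimated correlation. Csf1r, the receptor for macrophage colony-stimulating factor, was at 11.7 ± 5.35 and 33.9 ± 14.0 CPM. Cd5, a T-cell surface protein, was at 1.01 ± 0.218 and 3.25 ± 0.671 CPM, and Hba-a1, alpha globin, at 3.27 ± 1.41 and 8.47 ± 2.41 CPM. Adjusted over the list alone, 2 T-cell markers were called higher and 0 macrophage or erythroid markers. The 49 cytosolic ribosomal protein genes had a median of −0.10 (adjusted p = 0.00258; adjusted p = 0.998 with an estimated correlation). The NK cell identity list had a median of −0.07 (adjusted p = 0.468). The lowest adjusted p of the lists not called was 0.322, that of the inhibitory receptors.

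The comparison of cKO with WT in tumor asks how loss of the gene alters RNA levels in the samples labelled as NK cells of the tumor. Of 30 lists tested in tumor, camera called 12 at the preset correlation, 3 higher and 9 lower in cKO, and 0 with an estimated correlation (lowest adjusted p = 0.349). Bcl11b, a transcription factor of T-cell commitment (GRCm38 chromosome 12, 107910403 to 108003602), rose from 24.8 ± 4.77 CPM in WT to 121 ± 19.1 CPM in cKO (SD, n = 3 each; log2 2.28 ± 0.20 SE, adjusted p = 1.6e-05). Cd163 (chromosome 6, 124304656 to 124330527) fell from 614 ± 133 to 10.2 ± 1.22 CPM (log2 −5.91 ± 0.24, adjusted p = 3.06e-08). Xrcc6, the Ku70 subunit of DNA end joining, rose from 47.2 ± 9.77 to 228 ± 48.7 CPM (log2 2.27 ± 0.19). H2-Q2, a class I gene of the Q region, rose from 4.72 ± 1.29 to 48.4 ± 15.3 CPM (log2 3.34 ± 0.35).

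Of 16831 genes, 6399 were called in tumor, 2761 higher (43.1%) and 3638 lower, and 3584 of them changed at least 2-fold, 1194 up and 2390 down. The split depended on the scaling. Without a composition factor 3734 were higher (57.4%) and 2772 lower, and limma-trend on RPKM had 58.5% higher. The median log2 change of all genes was −0.117 with the composition factor and 0.055 without it. The other large rises were in Amy1, salivary amylase (log2 5.42 ± 0.68, from 1.15 ± 0.654 to 46.5 ± 41.3 CPM), and Myzap (2.48 ± 0.36, from 26.2 ± 4.27 to 146 ± 47.3 CPM). Rises of log2 2.32 or more were also seen in Map3k19 (2.77), Ccdc18 (2.43), Casc4 (2.34), Chst3 (2.32) and Cox6a2 (2.32). With the 6 tumor libraries alone Map3k19 (adjusted p = 0.0822) and Chst3 (0.0818) did not pass, and Map3k19 not by limma-trend either (0.0633). The other large falls were in Chil3, a chitinase-like protein of macrophages (log2 −6.83 ± 1.11, from 787 ± 902 to 6.91 ± 3.55 CPM), and the chemokine Ccl24 (−4.91 ± 0.67, from 1408 ± 301 to 46.8 ± 35.3 CPM). Large falls were also seen in Tmem26 (−6.95), Ear2, an eosinophil-associated ribonuclease (−5.79), the growth factor Igf1 (−4.79), Fcgrt (−4.15) and Atp6v0d2 (−4.12). The immunoglobulin segments Ighv4-1 (log2 −13.73 ± 3.15) and Ighj2 (−4.85) were high in tumor WT replicate 3, with an SD of 3730 around the mean of 2206 CPM of Ighv4-1 in tumor WT. Ighj2 did not pass without tumor cKO replicate 1 (adjusted p = 0.0621), 2 (0.0649) or 3 (0.0877), and Ighv4-1 not without tumor cKO replicate 3 (0.0529). Ighj2 did not pass with the 6 tumor libraries alone either (0.0527).

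Cell cycle genes rose together in tumor cKO. Of 40 tested, 36 rose, 1 fell and 3 did not pass, with 36 and 1 when adjusted over the list alone (median log2 1.56, camera adjusted p = 1.77e-17; adjusted p = 0.349 with an estimated correlation). Mki67 rose from 574 ± 135 to 2119 ± 342 CPM (log2 1.89 ± 0.19), and Mcm5, a subunit of the replicative helicase, from 82.2 ± 8.56 to 284 ± 50.5 CPM (1.79 ± 0.15). Mcm2 and Rrm1, a subunit of ribonucleotide reductase, rose by log2 1.76 and 1.63. Nutrient transport and mTORC1-MYC growth genes had 18 of 26 higher and 3 lower, 19 and 3 adjusted over the list alone (median 0.89, adjusted p = 4.27e-05; adjusted p = 0.349 with an estimated correlation). Phgdh, the first enzyme of serine synthesis, rose from 123 ± 14.7 to 377 ± 74.2 CPM (log2 1.61 ± 0.15). Shmt2 rose by 1.56 and the nucleolar gene Nop58 by 1.21. Of 39 oxidative phosphorylation genes 10 rose and 1 fell, the same numbers adjusted over the list alone (median 0.24, adjusted p = 0.00433; adjusted p = 0.495 with an estimated correlation). Atp5b, a subunit of ATP synthase, rose by 0.81 ± 0.14. T-cell markers moved with these groups: 5 of 15 rose and 2 fell, 7 and 2 adjusted over the list alone, while the list was not called (median 0.68, adjusted p = 0.084). Cd3d rose from 42.8 ± 4.95 to 92.3 ± 11.8 CPM (log2 1.11 ± 0.21) and Trac from 36.2 ± 3.53 to 81.4 ± 19.1 CPM (1.17 ± 0.25). Foxp3, the factor of regulatory T cells, fell from 25.5 ± 7.34 to 11.5 ± 3.2 CPM (−1.14 ± 0.26).

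NK cell identity genes fell on balance in tumor cKO, with 12 of 22 lower, 2 higher and 8 not passing, and 15 lower and 2 higher adjusted over the list alone (median log2 −1.47, adjusted p = 0.00433, and 0.38 with an estimated correlation). When each library was left out, the median lay between −1.66 and −0.97, the latter without tumor WT replicate 1. Cd244, the receptor 2B4, fell from 30.6 ± 13.7 to 7.72 ± 1.68 CPM (log2 −1.99 ± 0.30), and Nfil3, a factor of NK cell development, from 283 ± 56.2 to 80.6 ± 16.0 CPM (−1.81 ± 0.26). Fcgr3, an Fc receptor shared with macrophages, fell from 307 ± 123 to 55.4 ± 25.2 CPM (−2.47 ± 0.37). Tox, a factor of lymphocyte development, rose from 9.71 ± 2.43 to 30.8 ± 4.14 CPM (1.66 ± 0.22). Cytotoxic granule and death-ligand genes had 11 of 19 lower and 1 higher, the same adjusted over the list alone (median −1.02, adjusted p = 0.0231; adjusted p = 0.38 with an estimated correlation). Fasl, the Fas ligand, fell from 6.73 ± 2.83 to 1.70 ± 0.313 CPM, and the lysosomal genes Lamp1 and Ctsw had log2 changes of −1.79 and −1.78. IL-12 and IL-18 receptor signalling genes had 8 of 14 lower and 0 higher, also adjusted over the list alone (median −0.59, adjusted p = 0.0231; adjusted p = 0.349 with an estimated correlation). Stat3 changed by log2 −1.15 ± 0.11 and Il21r by −1.65 ± 0.24. In the same libraries 17 of 18 macrophage markers fell, and macrophages also express Fcgr3 and Lamp1. Nfil3, unlike Ncr1, was higher in tumor than in spleen in WT, so its fall here need not come from NK cells.

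Genes of the IL-15 receptor and JAK-STAT5 pathway had 12 of 26 lower and 3 higher in tumor cKO, the same adjusted over the list alone, and the list was not called (median log2 −0.50, adjusted p = 0.0769; adjusted p = 0.362 with an estimated correlation). Il2rb, the shared beta chain of the IL-2 and IL-15 receptors (GRCm38 chromosome 15, 78480553 to 78495066), fell from 72.9 ± 40.3 to 27.2 ± 5.08 CPM (log2 −1.42 ± 0.37, adjusted p = 0.0105), but did not pass with the 6 tumor libraries alone (log2 −1.37, adjusted p = 0.0526). Il2rg, the common gamma chain (chromosome X, 101264378 to 101268255), fell from 110.5 ± 13.2 to 55.9 ± 13.6 CPM (−0.98 ± 0.17, adjusted p = 0.000633). The kinase gene Jak1 changed by log2 −0.92, while Myc and the cyclin gene Ccnd2 rose by 0.90 and 1.06. Il15ra (5.98 and 8.75 CPM; log2 0.55 ± 0.38, adjusted p = 0.275) and the phosphatase gene Ptpn6 (375 and 430 CPM; 0.20, adjusted p = 0.259) did not pass, although Ptpn6 did without a composition factor (0.0479). Pdcd1, which encodes the inhibitory receptor PD-1 (chromosome 1, 94038305 to 94052553), rose from 55.9 ± 3.25 to 157 ± 27.6 CPM (log2 1.49 ± 0.53, adjusted p = 0.049). The T-cell genes Bcl11b, Cd3d and Trac rose in the same libraries, and these values do not show in which cells Pdcd1 rose. Gzmb, granzyme B (chromosome 14, 56258856 to 56262260), fell from 68.3 ± 41.2 to 24.4 ± 6.97 CPM (−1.49 ± 0.44, adjusted p = 0.0207). Prf1, perforin (chromosome 10, 61297836 to 61304263), fell from 18 ± 9.32 to 8.72 ± 1.72 CPM (−1.04 ± 0.34, adjusted p = 0.03). Ifng was at 2.61 and 3.39 CPM (log2 0.40, adjusted p = 0.4). In the same comparison 17 genes restricted to NK cells, most of them receptor genes, had a median log2 change of −1.49, with 12 called lower and 1 higher. The falls of Il2rb, Il2rg, Gzmb and Prf1 therefore cannot be told apart from a lower share of NK cell RNA.

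**Figure D2:**
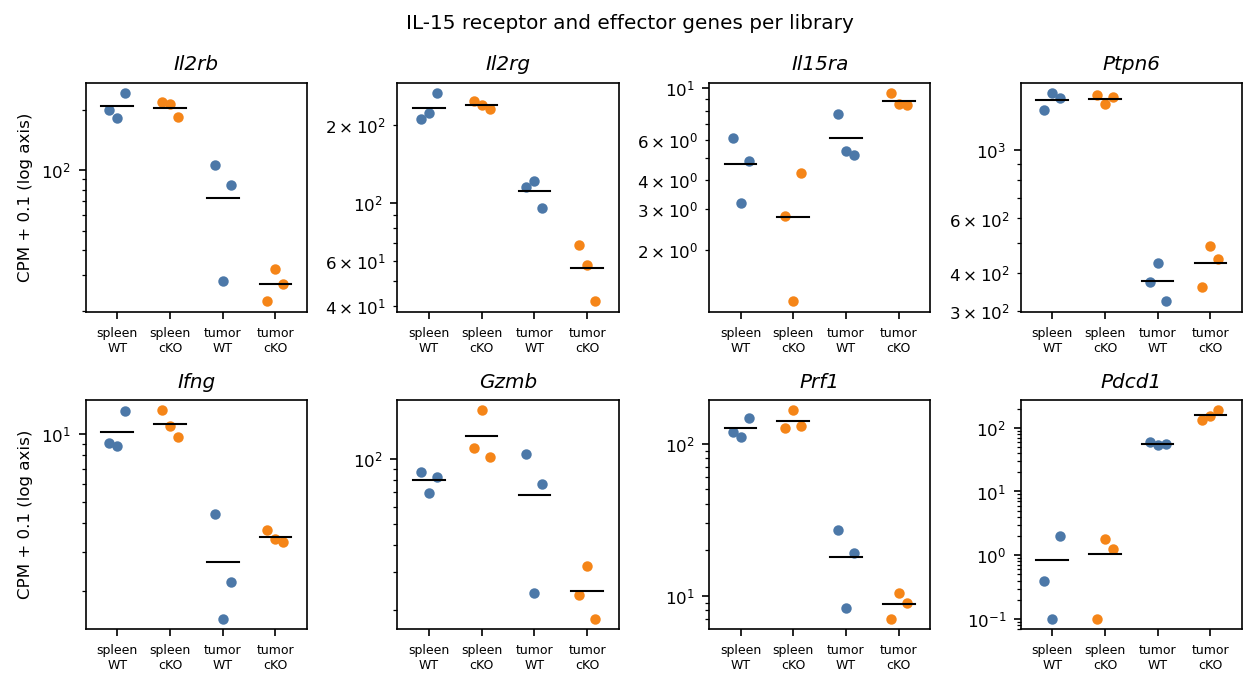
Levels of Il2rb, Il2rg, Il15ra, Ptpn6, Ifng, Gzmb, Prf1 and Pdcd1 in the 12 libraries, as CPM plus 0.1 on a log axis, with 1 point per library and a line at the group mean. In tumor, the mean of Il2rb was 72.9 CPM in WT and 27.2 CPM in cKO, and that of Pdcd1 55.9 and 157 CPM.

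The calls of Pdcd1, Gzmb and Prf1 depended on single libraries and on the fit. With the 6 tumor libraries alone Gzmb (adjusted p = 0.0677) and Prf1 (0.104) did not pass, nor by limma-trend (0.0646 and 0.108). Pdcd1 passed in both of these fits. Its tumor levels did not overlap, at 52.6 to 59.1 CPM in WT and 132 to 187 CPM in cKO. With the replicate block Pdcd1 (0.0657) and Prf1 (0.0585) did not pass, and without a composition factor Prf1 did not (0.059). Without both tumor WT replicate 2 and tumor cKO replicate 3 Pdcd1 did not pass (0.133). Pdcd1 in tumor did not pass without spleen WT replicate 1 (adjusted p = 0.0636), spleen cKO replicate 2 (0.0549) or 3 (0.0733), tumor WT replicate 1 (0.1), 2 (0.0878) or 3 (0.105), or tumor cKO replicate 1 (0.0752), 2 (0.0949) or 3 (0.136), nor by DESeq2 (0.361). Gzmb in tumor did not pass without tumor WT replicate 1 (0.0836) or 3 (0.0612) or tumor cKO replicate 1 (0.0631) or 3 (0.101). Prf1 in tumor did not pass without tumor WT replicate 1 (0.136) or 3 (0.0805) or tumor cKO replicate 1 (0.0989) or 3 (0.0891). Ifng in tumor passed without tumor WT replicate 1 (log2 0.97, adjusted p = 0.0309).

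Inhibitory receptors and exhaustion-linked genes fell on balance although Pdcd1 rose, with 13 of 19 lower and 3 higher, also adjusted over the list alone (median log2 −1.47, adjusted p = 0.0146; adjusted p = 0.379 with an estimated correlation). Cblb, an E3 ligase that restrains lymphocyte activation, fell from 56.1 ± 6.0 to 15.2 ± 2.31 CPM (log2 −1.88 ± 0.14). Nr4a2 fell from 265 ± 95.4 to 60.6 ± 23.6 CPM (−2.13 ± 0.34), and the checkpoint gene Vsir had a log2 change of −1.80. TGF-beta response and tissue residency genes had 13 of 20 lower and 2 higher, the same adjusted over the list alone (median −1.01, adjusted p = 0.00433; adjusted p = 0.349 with an estimated correlation). Tgfbr2, the type 2 receptor, fell from 89.9 ± 13.5 to 28.7 ± 5.36 CPM (−1.65 ± 0.15) and the inhibitory Smad7 had a change of −1.72. Homing and adhesion receptors had 11 of 19 lower and 1 higher, also adjusted over the list alone (median −0.87, adjusted p = 0.0199; adjusted p = 0.513 with an estimated correlation). The integrin gene Itga4 changed by −1.16 and the sphingosine phosphate receptor gene S1pr5 rose by 1.13. Immediate-early and dissociation-stress genes had 15 of 25 lower and 1 higher, the same adjusted over the list alone (median −0.97, adjusted p = 0.000691; adjusted p = 0.38 with an estimated correlation). Klf6 changed by −1.31 and Ppp1r15a by −1.41. Macrophages, whose markers fell in the same libraries, also express many of these genes.

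The remaining functional lists were not called in tumor. Hypoxia genes had 10 of 20 lower and 3 higher (adjusted p = 0.127), with Vegfa falling from 1226 ± 45.2 to 427 ± 117 CPM. Glycolysis genes had 7 of 20 lower and 5 higher (0.94), with the glucose transporter gene Slc2a3 at log2 1.25 and the hexokinase gene Hk2 at −1.17. Mature NK cell genes had 9 of 15 lower and 2 higher (adjusted p = 0.117). Immature NK cell genes had 6 of 17 lower and 5 higher (0.906), with Tcf7 at log2 1.68, Sox4 at 1.72 and Thy1 rising from 340 ± 38.1 to 863 ± 151 CPM. Cytokines and chemokines had 4 of 16 lower (adjusted p = 0.293), and interferon-stimulated genes 6 of 33 lower and 1 higher (0.206). Apoptosis and p53 genes had 5 of 22 lower and 4 higher (adjusted p = 0.454), partners of SCF ubiquitin ligases 3 of 14 lower and 4 higher (0.452), and ribosomal proteins 5 of 49 higher and 1 lower (0.084). Adjusted over the list alone, the counts of lower and higher genes were 12 and 4 for hypoxia, 7 and 5 for immature NK cell genes, 3 and 0 for cytokines, 5 and 0 for interferon-stimulated genes, and 0 and 4 for ribosomal proteins. The counts of the other 4 lists did not differ.

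Markers of several other cell types were lower in tumor cKO. Of 18 monocyte and macrophage markers 17 fell and 0 rose by edgeR, 18 and 0 adjusted over the list alone (median log2 −2.72, adjusted p = 4.3e-07; adjusted p = 0.362 with an estimated correlation). Mrc1, the mannose receptor, fell from 1710 ± 420 to 109 ± 60.9 CPM (log2 −3.97 ± 0.46). Apoe, the lipid carrier, changed by −2.84. Dendritic cell markers had 10 of 14 lower, also adjusted over the list alone (median −1.93, adjusted p = 0.000691; adjusted p = 0.362 with an estimated correlation). Cd74, the invariant chain of class II molecules, fell from 4083 ± 965 to 959 ± 381 CPM. The other marker lists were not called. Fibroblast markers had 8 of 14 lower and 1 higher (median −2.79, adjusted p = 0.084), with Fn1, fibronectin, at −2.78. B-cell and plasma-cell markers had 4 of 16 lower and 4 higher (adjusted p = 0.206), with Cd22 at −2.22 and Ighd at 2.18. Endothelial markers had 3 of 11 lower (adjusted p = 0.256), with Pecam1 at −1.33. Platelet markers had 3 of 6 lower (adjusted p = 0.084), neutrophil markers 2 of 10 lower and 1 higher (0.395), erythroid markers 1 of 8 lower (0.887), and epithelial markers 2 of 6 lower (0.293). The 3 melanoma markers tested all fell (median −2.03) and were too few for a list test.

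**Figure D3:**
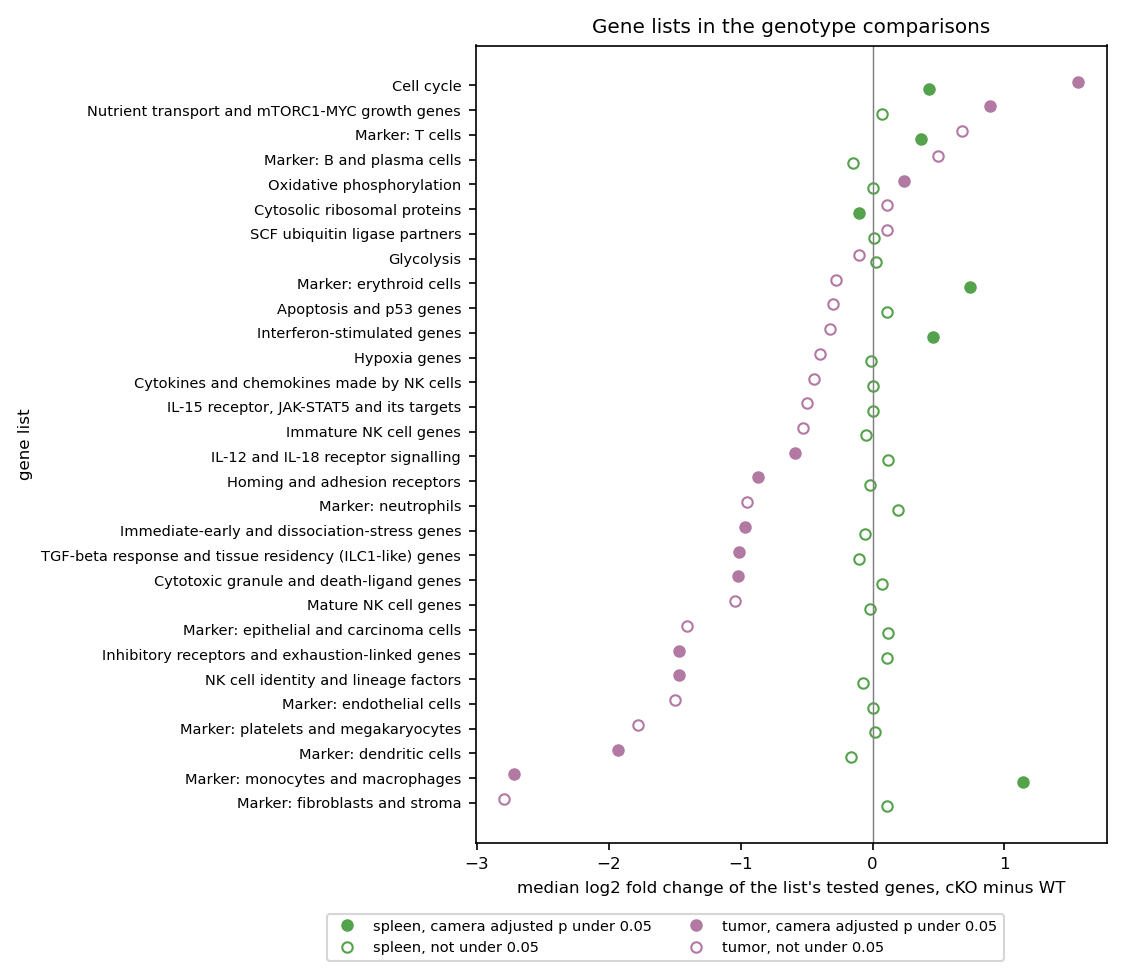
Median log2 fold change of cKO against WT for each of 30 gene lists, in spleen (green) and tumor (purple), with filled points for lists with a camera adjusted p under 0.05 at the preset correlation. Cell cycle genes had medians of 0.43 in spleen and 1.56 in tumor, and macrophage markers 1.14 in spleen and −2.72 in tumor.

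The 6 tumor libraries alone gave 5383 calls, 2659 higher and 2724 lower, of which 4960 were among the 6399. In simulated counts 28.8% of the tumor calls of the 12-library fit were unchanged genes, against 3.5% with the 6 tumor libraries alone. That simulation changed 200 genes and gave 156 calls in the 12-library fit, so these shares do not carry over to the 6399 real calls. With a macrophage score of each library as a covariate, chosen after seeing the data, 1 gene was called. This score alone separated the genotypes, with 8.46 to 9.18 in tumor WT and 5.29 to 6.81 in tumor cKO, and 1.45 to 2.28 in spleen WT and 2.69 to 2.99 in spleen cKO. The lost calls therefore do not show that the changes went away. With the covariate the log2 values were 6.57 for Amy1, 3.09 for Ccdc18 and 2.01 for Xrcc6, but −0.38 for Atp6v0d2, −1.24 for Igf1 and 0.34 for Pdcd1.

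The comparison of tumor with spleen in WT asks how the samples labelled as NK cells of the tumor differ from those of the spleen. Ncr1 fell from 162 ± 38.5 CPM in spleen to 1.75 ± 0.117 CPM in tumor (SD, n = 3 each; log2 −6.53 ± 0.28 SE, adjusted p = 2.6e-09). Pax5 (GRCm38 chromosome 4, 44524757 to 44710487) fell from 568 ± 78.9 to 1.49 ± 1.87 CPM (−8.36 ± 0.84), and Vegfa, the angiogenic growth factor, rose from 5.32 ± 0.427 to 1226 ± 45.2 CPM (7.85 ± 0.24). Cxcl2, a neutrophil-attracting chemokine (chromosome 5, 90903871 to 90905938), had no reads in spleen WT and was at 1770 ± 1110 CPM in tumor WT, at least 18000-fold higher. Of 16831 genes 10437 were called, 5711 higher and 4726 lower in tumor, and 7577 changed at least 2-fold.

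Genes with no reads in spleen WT made up most of the named rises in WT. By the floor, F10, coagulation factor X, was at least 9820-fold higher in tumor, Rhox5 at least 3640-fold, and Nlrp3, the inflammasome sensor, at least 3070-fold. Chil3 (chromosome 3, 106147554 to 106167564), Mmp12, macrophage elastase, Slc7a2 and Ptpro were at 787, 522, 402 and 60.9 CPM in tumor WT. Thbs1, thrombospondin, rose from 0.518 to 3480 CPM (log2 12.77 ± 0.74) and Anpep by log2 12.33. The 10 named falls were in genes of B cells or their immunoglobulins, except Chst3 (−9.62). Fcer2a fell from 402 to 0.376 CPM (−9.82 ± 0.64) and Ms4a1, which encodes CD20, from 360 to 0.756 CPM (−8.76). Cr2 (−9.74), Fcmr (−9.43), Ighd (−9.33), Iglc2 (−8.45), Iglj2 and Iglj3 fell as well.

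Of 30 lists tested in WT, 16 were called, 13 higher and 3 lower in tumor. NK cell identity genes had 14 of 22 lower and 6 higher (median log2 −2.11, adjusted p = 0.00662; adjusted p = 0.433 with an estimated correlation). Klrd1, the CD94 receptor, changed by −4.23 and Cd160 by −4.72, and Nfil3 rose by 4.26. Homing receptors had 12 of 19 lower and 5 higher (−1.30, adjusted p = 0.019; adjusted p = 0.454 with an estimated correlation). All 20 glycolysis genes (median 2.53, adjusted p = 7.34e-09; adjusted p = 0.17 with an estimated correlation) and all 20 hypoxia genes (2.49, adjusted p = 1.16e-07; adjusted p = 0.121 with an estimated correlation) rose. Pkm, pyruvate kinase, rose by 2.64, Pgk1 by 3.36 and Ldha by 2.44. Oxidative phosphorylation genes had 27 of 39 higher (median 0.94, adjusted p = 1.21e-05), nutrient and growth genes 19 of 26 higher and 2 lower (0.75, adjusted p = 0.00167). Both had an adjusted p of 0.34 with an estimated correlation. Cell cycle genes had 28 of 40 higher (0.90, adjusted p = 0.000693) and immediate-early genes 16 of 25 higher and 3 lower (2.0, adjusted p = 0.00684, with Nr4a1 at 3.46). Both had an adjusted p of 0.454 with an estimated correlation. Inhibitory receptors had 14 of 19 higher and 3 lower (3.02, adjusted p = 0.0135; adjusted p = 0.407 with an estimated correlation), with Havcr2, the receptor TIM-3, at 6.92. Apoptosis genes had 16 of 22 higher and 4 lower (1.40, adjusted p = 0.0108; adjusted p = 0.17 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 8.23. For these lists the counts adjusted over the list alone were the same as those over all genes.

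Markers of other cell types moved with these groups in WT. All 18 macrophage markers rose (median log2 6.79, adjusted p = 3.28e-08; adjusted p = 0.34 with an estimated correlation), with Arg1, arginase, from 4.05 ± 0.597 to 7092 ± 1670 CPM. All 14 fibroblast markers rose (7.25, or 6.75 with groups without reads at their floor, adjusted p = 0.000162; adjusted p = 0.407 with an estimated correlation). Neutrophil markers had 8 of 10 higher (4.52, adjusted p = 0.0135) and endothelial markers 9 of 11 higher and 1 lower (6.91, or 5.33 at the floor, adjusted p = 0.0146). T-cell markers had 8 of 15 higher and 1 lower (1.16, adjusted p = 0.0355, with Trac at 3.04). All 3 lists had an adjusted p of 0.454 with an estimated correlation. B-cell and plasma-cell markers had 13 of 16 lower and 1 higher (−6.96, adjusted p = 2.18e-07; adjusted p = 0.17 with an estimated correlation). The counts adjusted over the list alone were again the same. Of the lists not called, cytotoxic genes had 10 of 19 lower and 6 higher (adjusted p = 0.239), and TGF-beta genes 13 of 20 higher and 5 lower (0.0955). IL-15 pathway genes had 12 higher and 12 lower of 26, with a positive median of 0.32 and a downward camera direction (adjusted p = 0.924).

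In cKO, tumor differed from spleen in 10183 genes, 5332 higher and 4851 lower. Cxcl2 and Rhox5 had no reads in spleen cKO. Cxcl2 was at least 12600-fold higher in tumor cKO and Rhox5 was at 1040 CPM there, and Thbs1 (log2 10.92 ± 0.70) and F10 (8.91) rose here too. Fcer2a, Cr2, Ms4a1 and Pax5 changed by log2 −7.52, −8.02, −7.10 and −7.19. Chil3 had a log2 value of 2.84 ± 1.23 and did not pass (adjusted p = 0.0791). It passed with the cKO libraries alone (0.00864), by DESeq2 (0.0189), by limma-trend (0.0188), with the block within genotype (0.000215) and without a filter (1.52e-35). It also passed without tumor WT replicate 1 (0.0469) or 2 (0.0234), and without both tumor WT replicate 2 and tumor cKO replicate 3 (0.0273). Without a filter the log2 value of Chil3 was 2.917, close to that above, so its adjusted p there is weak evidence. Of 30 lists 17 were called, 11 higher and 6 lower. Cell cycle genes had 38 of 40 higher (median 1.75, adjusted p = 1.9e-10; adjusted p = 0.306 with an estimated correlation) and NK cell identity genes 15 of 22 lower and 5 higher (−3.39, adjusted p = 0.000862; adjusted p = 0.306 with an estimated correlation). Nutrient and growth genes had 24 of 26 higher (1.59, adjusted p = 9.31e-08), glycolysis genes 19 of 20 (2.36, adjusted p = 8.72e-10) and hypoxia genes 16 of 20 (2.18, adjusted p = 3.98e-07). IL-12 and IL-18 genes had 10 of 14 lower and 2 higher (−1.33, adjusted p = 0.00259). Each of these 4 lists had an adjusted p of 0.118 with an estimated correlation. Cytotoxic genes had 12 of 19 lower and 5 higher (−1.56, adjusted p = 0.0271; adjusted p = 0.404 with an estimated correlation). Macrophage markers had 15 of 18 higher (2.81, adjusted p = 0.000474; adjusted p = 0.453 with an estimated correlation). B-cell markers had 15 of 16 lower (−6.55, adjusted p = 1.23e-07; adjusted p = 0.118 with an estimated correlation) and erythroid markers 6 of 8 lower (−2.33, adjusted p = 0.00997; adjusted p = 0.306 with an estimated correlation). Adjusted over the list alone, 20 glycolysis genes and 16 macrophage markers were higher, 11 IL-12 and IL-18 genes lower, and 6 cytotoxic genes higher.

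Most tissue differences were shared by the genotypes. Of the genes called higher in tumor, 3954 were shared by WT and cKO, with 1809 expected by chance, and of those called lower 3521 were shared, with 1362 expected. In the opposite direction 105 and 116 genes were called. Across genes the log2 fold changes of the 2 genotypes had a Pearson r of 0.839 and a Spearman rho of 0.822, although genes are not independent replicates.

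The difference of the cKO effects between the tissues asks whether the loss acts differently in tumor and spleen. Amy1 (GRCm38 chromosome 3, 113555710 to 113606699) and H2-Q2 had the largest positive differences, log2 5.16 ± 0.89 (adjusted p = 0.00417) and 3.44 ± 0.56 (adjusted p = 0.003). They were followed by the troponin gene Tnnt1 (3.19 ± 0.69, adjusted p = 0.00933; tumor means 25.7 and 86.1 CPM), the proton pump gene Atp6v1g3 (3.01 ± 0.49, adjusted p = 0.00297; 10.8 and 32.2 CPM) and Cand2, an exchange factor of cullin ligases (2.80 ± 0.73, adjusted p = 0.0199). Among the genes named for a negative difference were Ighv4-1 (log2 −14.85, adjusted p = 0.0236) and Ear2 (−7.02, adjusted p = 0.00384). Chil3 (adjusted p = 0.0269), Slc7a2 (0.0427) and F10 (0.0442) also had a more negative effect in tumor. They had no reads in spleen WT, so their fitted values (log2 −13.90, −11.15 and −7.98) are no bounds and give no rank. In all, 3072 genes were called, 1293 with a more positive effect in tumor (42.1%) and 1779 with a more negative one. Without a composition factor these were 1877 (57.8%) and 1372, and limma-trend had 59.2% positive.

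Some gene calls of the difference depended on single libraries, and that of Ighv4-1 on the replicate block as well (log2 −13.38, adjusted p = 0.0948 with it). Cand2 did not pass without spleen cKO replicate 1 (adjusted p = 0.052) or 2 (0.0514), and Chil3 not without spleen cKO replicate 1 (0.163) or 2 (0.0635) or tumor cKO replicate 3 (0.0928). Ighv4-1 did not pass without spleen WT replicate 1 (0.0597), 2 (0.0599) or 3 (0.0563), spleen cKO replicate 1 (0.0554), or tumor cKO replicate 1 (0.0644), 2 (0.052) or 3 (0.0856). Slc7a2 did not pass without spleen WT replicate 1 (0.0698), 2 (0.0699) or 3 (0.0596), spleen cKO replicate 1 (0.0823), 2 (0.0893) or 3 (0.1), or tumor cKO replicate 2 (0.07) or 3 (0.0994). F10 did not pass without spleen WT replicate 1 (0.0723), 2 (0.072) or 3 (0.0624), spleen cKO replicate 1 (0.125) or 2 (0.0744), tumor WT replicate 1 (0.0808), 2 (0.105) or 3 (0.0814), or tumor cKO replicate 2 (0.0591).

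Of 30 lists 14 differed between the tissues by camera. Cell cycle genes had 20 of 40 with a more positive effect in tumor, 27 with 1 more negative adjusted over the list alone (median log2 1.14, adjusted p = 1.69e-10; adjusted p = 0.361 with an estimated correlation). Nutrient and growth genes had 11 of 26 more positive and 2 more negative, 13 and 2 alone (0.65, adjusted p = 0.000377; adjusted p = 0.337 with an estimated correlation). Macrophage markers had 13 of 18 with a more negative effect in tumor, 15 adjusted over the list alone (−3.28, adjusted p = 4.22e-10; adjusted p = 0.337 with an estimated correlation), with Mrc1 at −5.53 ± 0.63. Inhibitory receptors had 6 of 19 more negative and 1 more positive, 11 and 2 alone (−1.64, adjusted p = 0.00432), and cytotoxic genes 5 of 19, 10 with 1 more positive alone (−1.28, adjusted p = 0.012). NK cell identity genes had 8 of 22 more negative with 2 more positive, 10 and 2 alone (−1.10, adjusted p = 0.0139), and immediate-early genes 8 of 25, 12 with 1 more positive alone (−1.08, adjusted p = 0.00302). With an estimated correlation their adjusted p was 0.337, 0.383, 0.476 and 0.476. Gzmb had a difference of −2.16 ± 0.61 (adjusted p = 0.0325), and IL-15 pathway genes were not called as a list (−0.61, adjusted p = 0.0738).

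The average of the cKO effects over both tissues asks how the loss alters RNA levels on the mean of both. A large effect in tumor alone can give a call, so a call does not show a change in each tissue. Clspn, the checkpoint adaptor claspin, was at 37.2 ± 5.15 and 68.4 ± 19.8 CPM in spleen WT and cKO and at 108 ± 24.5 and 461 ± 75.6 CPM in tumor WT and cKO (average log2 1.49 ± 0.15, adjusted p = 0.000196). Kif18b, a mitotic kinesin (1.71), Mnd1 (1.67), the cell cycle repressor E2f7 (1.58), Melk (1.43) and the condensin gene Ncapg (1.38) rose as well. So did Mms22l (1.37) and Rad51ap1 (1.36 ± 0.13), both of homologous recombination, Bcl11b (1.38) and the choline dehydrogenase gene Chdh (2.13 ± 0.35, adjusted p = 0.00216). The largest falls were in Rcn3 (−2.05 ± 0.28), Pon3 (−1.92), Slc36a4 (−1.76), Klf4 (−1.68), Mir22hg (−1.61), Tlcd2 (−1.61), Maml2 (−1.40), Csrp2 (−1.36) and the inhibitory Fc receptor Fcgr2b (−1.36). In all, 3420 genes were called, 1573 higher (46%) and 1847 lower, and without a composition factor 2291 (64.7%) and 1249.

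Of 30 lists 10 were called for the average. Cell cycle genes had 35 of 40 higher, 38 with 1 lower adjusted over the list alone (median log2 0.96, adjusted p = 7.86e-23), nutrient and growth genes 15 of 26 higher and 3 lower, 18 and 3 alone (0.47, adjusted p = 3.67e-05). Both had an adjusted p of 0.413 with an estimated correlation. T-cell markers had 6 of 15 higher and 1 lower, 7 and 1 alone (0.35, adjusted p = 0.0158; adjusted p = 0.497 with an estimated correlation). NK cell identity genes had 9 of 22 lower and 1 higher, 10 and 1 alone (−0.68, adjusted p = 0.0033), immediate-early genes 11 of 25 lower, 12 with 1 higher alone (−0.38, adjusted p = 0.000606). TGF-beta genes had 8 of 20 lower, 10 with 1 higher alone (−0.57, adjusted p = 0.00578), and dendritic cell markers 8 of 14 lower (−1.05, adjusted p = 0.000606). All 4 of these lists had an adjusted p of 0.439 with an estimated correlation. Macrophage markers had 7 of 18 lower, 8 alone (−0.76, adjusted p = 0.00109, and 0.497 with an estimated correlation), although their medians were of opposite sign in spleen and tumor. The nutrient and growth, NK cell identity, immediate-early, TGF-beta and dendritic cell lists were not called in spleen. Their average calls therefore do not show a change there.

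Of the 5 genes called higher in spleen, 4 were called higher in tumor, with 0.82 expected (one-sided Fisher's exact p = 0.00314), and no gene was called lower in both. The 4 were Rps15a-ps6 and Rps15a-ps7, pseudogenes of the same gene, and Tcrg-C2 and Trgj2, segments of the same locus. Fisher's exact test counts them as independent genes, so its p-value is too small. At an unadjusted p under 0.01, 40 of the 135 genes higher in spleen were also higher in tumor, with 19.18 expected (one-sided Fisher's exact p = 2.76e-06). Of the 48 lower in spleen, 6 were lower in tumor, with 8.889 expected (one-sided Fisher's exact p = 0.902). Without spleen WT replicate 1, 2 or 3, or spleen cKO replicate 2 or 3, 0 genes were shared, and without spleen cKO replicate 1 or tumor cKO replicate 1 or 2, 1 was. Across all genes the log2 fold changes of the tissues had a Pearson r of −0.022 and a Spearman rho of 0.038.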

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

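Tests chosen only after the result was seen were the median of NK-restricted genes and the count without tumor WT replicate 2 in the first pattern, both tests of the second pattern, and the count of low p-values on chromosome 7 in the third.

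The cKO effect differed between tumor and spleen, by the test of the difference itself, for 3072 genes and 14 lists. Among the named genes the difference in log2 was 5.16 for Amy1, 3.44 for H2-Q2, 3.19 for Tnnt1, 3.01 for Atp6v1g3 and 2.80 for Cand2, and −14.85 for Ighv4-1, −13.90 for Chil3, −11.15 for Slc7a2, −7.98 for F10 and −7.02 for Ear2. Chil3, Slc7a2 and F10 had no reads in spleen WT, so their fitted values are no bounds. Lists with a more positive effect in tumor were cell cycle (median difference 1.14), nutrient transport and mTORC1-MYC growth (0.65), oxidative phosphorylation (0.26) and cytosolic ribosomal proteins (0.21). Lists with a more negative effect were macrophage markers (−3.28), dendritic cell markers (−1.69), inhibitory receptors (−1.64), cytotoxic genes (−1.28), NK cell identity (−1.10), immediate-early genes (−1.08), TGF-beta response (−0.88), IL-12 and IL-18 signalling (−0.83), homing receptors (−0.74) and interferon-stimulated genes (−0.74). With an estimated correlation none of the 14 was called, and their lowest adjusted p was 0.337.

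In the first pattern, cell cycle and growth genes were higher and macrophage genes lower in tumor cKO than in tumor WT. A smaller share of macrophage RNA alone would raise the markers of all other cells alike, but 17 NK-restricted genes, most of them receptor genes, had a median log2 change of −1.49, between −1.80 and −1.25 when each library was left out, which argues against it (12 were called lower, and Klra1 higher); nor did the call count rest on the deepest library, with 6721 genes without tumor WT replicate 2. The values that RNA of 1 T-lineage clone with a larger share in cKO needs are there. Trbv15, a variable segment of the T-cell receptor beta chain, took a median of 94.3% of Trbv reads in the 6 tumor libraries and at most 5% in spleen, and was at 35.8 to 48.4 CPM in tumor WT and 64.5 to 87.1 CPM in tumor cKO. Its log2 change of 0.79 was smaller than that of the cell cycle list (1.56) and of Bcl11b (2.28). Some other T-lineage or tumor-only genes rose more than Trbv15. Trgv2 was at 54.9 to 74.7 CPM in tumor WT and 176 to 241 CPM in tumor cKO. Rhox5, without reads in spleen, had means of 300 and 1040 CPM. Dntt, also without reads in spleen, rose more than Trbv15 as well. The Y-chromosome genes given further below, chosen after their values were seen, fell in tumor cKO. Foxp3 and the delta segment Trdv4 did not rise. The size of such a share therefore cannot be read from Trbv15 alone, and an effect of the knockout on the NK cells or on the tumor stays open and untested.

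In the second pattern, NK cell genes were lower in tumor than in spleen libraries, which is not explained by depth, since the tumor library with the fewest counts held 15.8 M and the spleen library with the most 13.8 M. Dilution by RNA of other cells would lower all NK-restricted genes by a similar factor. In WT, 16 of 17 such genes were lower in tumor, with a median log2 change of −3.17, that is 11.1% of the spleen level, and an interquartile range of 1.61. The lower genes ranged from −6.53 for Ncr1 to −1.19 for Klrb1b, so they did not follow 1 common factor. The exception was Klra1, at 13.8 CPM in spleen WT, 17.1 in tumor WT and 51.9 in tumor cKO, and T-lineage cells can express genes of this receptor family as well. The spleen libraries held B-cell RNA too, with Pax5 at 568 CPM and Ncr1 at 162 CPM in WT. Their level is therefore not that of NK cells alone. How much of the fall came from dilution and how much from lower expression within NK cells cannot be told here, because no library gives the number of NK cells.

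In the third pattern, 2 pseudogenes of Rps15a, Rps15a-ps6 and Rps15a-ps7, were called higher in spleen cKO and Rps15a was lower, past the threshold by DESeq2 but not by edgeR, while Rps15a-ps2 and Rps15a-ps4, at 0.365 CPM or less, had lower means. Of the 29 genes with an unadjusted p under 0.001 in spleen, 5 lay on 1 stretch of chromosome 7 that holds Rps15a (0.5 expected), but the stretch was chosen for holding them, and chromosomes 6 and 9 held 5 each. If reads only moved between Rps15a and its pseudogenes, their summed level would hold, but in spleen it went from 138 ± 9.57 to 102 ± 19 CPM, a log2 ratio of −0.43, between the bounds set in advance for and against shared reads. In tumor WT and cKO, Rps15a was at 143 and 141 CPM and the sum at 145 and 148 CPM. Rps15a-ps6 (0.239 and 2.4 CPM) and Rps15a-ps7 (0.311 and 3.52 CPM) were called higher in tumor cKO as well. A stretch of another strain's sequence around the genes may shift reads in the same direction in tumor, but 2 of the 5 genes did so, 40% (95% exact interval 5.3% to 85.3%). That share lay on the side set in advance against it, but with 5 genes its interval covers both sides. None of the 5 was called in tumor (edgeR adjusted p from 0.108 to 0.836), so their directions there carry little information. Trim12a of the same stretch, not among the 5, was lower in cKO in both tissues. Its means were 236 and 81.8 CPM in spleen and 26.6 and 12.9 CPM in tumor. The share of 40% therefore cannot weigh against a strain stretch, and both explanations stay open.

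The libraries of each comparison were also split in all other ways into groups of the same sizes. With 3 against 3 libraries there are 10 splits, so the share of splits with as many calls can never be under 0.1. For genes, 1 of 10 splits, the real one, gave as many calls in spleen (5, highest other 0), in tumor (6399, highest other 0), for tumor against spleen in WT (10437, highest other 0) and in cKO (10183, highest other 0). For lists, 1 of 10 gave as many in spleen (6, highest other 5), 4 of 10 in tumor (12, highest other 18), 1 of 10 for tumor against spleen in WT (16, highest other 14) and 1 of 10 in cKO (17, highest other 15). For the average and the difference, 100 of 200 splits were drawn. For the average over tissues 1 of 100 splits gave as many genes (3420, highest other 3185), but only the 8 splits that kept the tumor groups called any, so this share restates the tumor grouping, for which 10 splits are too few. For its lists 44 of 100 gave as many (10, highest other 16), so chance was not excluded. For the difference 6 of 100 splits gave as many genes (3072, highest other 3420) and 11 of 100 as many lists (14, highest other 16). All 6 kept the real tumor groups. The split with 3420 also kept the real spleen groups with the tumor labels swapped, which makes it the real average. The share for genes therefore restates the tumor grouping and cannot speak to chance, and for lists chance was not excluded. Among splits that did not keep the real tumor groups the highest gene count was 0 by edgeR for both comparisons.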

How the results depend on the processing

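Chosen after seeing the data were the fit without tumor WT replicate 2 and tumor cKO replicate 3 and the macrophage covariate, which is confounded with genotype in both tissues. In spleen the 5 genes became 230 without a filter, 31 with the spleen libraries alone, 46 by DESeq2, 34 without the 2 libraries that stood apart, 8 by limma-trend, 2 with the replicate block, 0 with the covariate (784 at an unadjusted p under 0.05 in the edgeR fit without it), and 0 to 8 when 1 library was left out. The named spleen genes that passed only without a filter kept nearly the same log2 values, so the count of 230 is weak evidence. The calls shared by spleen and tumor ranged from 0 to 4. With the covariate 1 gene was called in tumor, 1 for the difference and 198 for the average; a fold of at least 2 left 3584 genes in tumor and 721 for the average. The other counts, under these and the remaining alternatives apart from leaving out 1 library, stayed within 1.5 times: 5383 to 7137 in tumor, 7577 to 10846 for the tissues in WT, 7230 to 10625 in cKO, 2106 to 4179 for the difference and 2983 to 4374 for the average. Leaving out 1 library gave 4410 to 6721 genes in tumor, 9586 to 10705 for the tissues in WT and 9224 to 10933 in cKO. It gave 2140 to 4059 for the difference and 2400 to 4401 for the average. With an estimated correlation 0 lists were called in each comparison; fry called 0 in spleen, 18 in tumor, 26 for the tissues in WT and 16 for the average. Reversed in sign, without passing, were Il2rb in spleen (0.002 by limma-trend, 0.35 with the covariate, −0.11 to 0.10 over left-out libraries), Il2rg in spleen (−0.19 with the covariate, −0.031 to 0.139), Pdcd1 in spleen (−0.21 to 2.51), Ptpn6 in spleen (−0.035 to 0.058) and Ifng in tumor (−0.34 with the covariate). The cause was not tested, except that fewer libraries or genes were used where these were left out. Of the values of named genes under the alternatives, 372 of 417 in spleen, 552 of 614 in tumor, 440 of 440 for the tissues in WT, 432 of 440 in cKO, 169 of 209 for the difference and 407 of 420 for the average kept direction and side of the threshold. The alternatives for the gene that was knocked out were not run. Depth limits genes near the floor, 0.0434 to 0.0811 CPM.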

Other observations

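Dntt, which encodes the terminal transferase of developing lymphocytes, had no reads in spleen and rose in tumor from 6.12 ± 2.16 CPM in WT to 73.4 ± 32.3 CPM in cKO (SD, n = 3 each; log2 3.57 ± 0.43, adjusted p = 0.000511). Trgv2, a variable segment of the gamma chain, rose from 63.2 ± 10.3 to 200.2 ± 35.6 CPM (log2 1.66 ± 0.27), and Tcrg-C1 and Tcrg-C2 rose by 1.52 ± 0.35 and 1.32 ± 0.15. Trdv4, the top variable gene of the delta chain in every library, was at 11.7 to 18.3 CPM in spleen and 0.361 to 2.27 CPM in tumor. Trdc, the constant region of that chain, fell in tumor from 3.06 ± 1.91 to 0.630 ± 0.0928 CPM (−2.24 ± 0.44). Trav13n-4 was the top alpha-chain variable gene in all 6 tumor libraries, with 23.9% to 42% of Trav reads. Cd4 and Cd8a did not pass in tumor (log2 −0.13, adjusted p = 0.829, and −0.19, adjusted p = 0.894). These genes were chosen after their values were seen.

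Rhox5, an X-linked homeobox gene (GRCm38 chromosome X, 37804842 to 37808876), had no reads in the 6 spleen libraries and was at 299.6 ± 16.2 CPM in tumor WT and 1040 ± 194 CPM in tumor cKO (log2 1.80 ± 0.15, adjusted p = 6.14e-05). Of the 11 Y-chromosome genes tested, 4 are given here, and they and the other genes of this paragraph were chosen after their values were seen. Ddx3y was at 113 CPM in spleen WT, 109.6 in spleen cKO, 96.1 ± 4.38 in tumor WT and 27.7 ± 13.4 in tumor cKO (tumor log2 −1.80 ± 0.29, adjusted p = 0.000677). Kdm5d, Eif2s3y and Uty changed in tumor by −1.90 ± 0.28, −1.47 ± 0.35 and −2.02 ± 0.38. The receptor gene Klre1 and the transcription factor gene Eomes changed in tumor cKO by −1.67 and −1.66, and Klra1 had a log2 value of 1.60.

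Libraries of the same replicate number did not deviate together across groups. After group means were removed their correlations lay between −0.088 and 0.111, against −0.08 to 0.116 for libraries of different numbers. This does not show whether a number marks a shared animal or day. The spread between libraries of a group was larger than sampling noise in all 4 groups, with a chi-square per degree of freedom of 6.38 to 162.4.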
